A study of Mus musculus with 15 samples.

How the data were processed

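RNA from frozen kidneys of male C57/BJ mice, 100 ng per sample, was labelled with Cy3 and hybridised to 1-colour Agilent 4x44K arrays (design 026655), per the labels' protocols and the file headers. In all, 15 arrays in 4 groups were used: low-fat sham (4), low-fat with 1 kidney (4), high-fat sham (3) and high-fat with 1 kidney (4). The intensity (signal) values of each array were made by the authors with Agilent Feature Extraction 10.7 per the submitters' processing notes, and 10.7.3.1 per the file headers. These deposited signals are background-subtracted and detrended within each array, per the file headers, with no normalization between arrays. The authors' deposited value table holds the same intensity signals after rounding, at 0.995 to 1.005 times the scanner files' processed signal, so no further scaling or centring was made. Its column medians ran from 56.7 to 251. The raw median spot and background intensities deposited in the same files served 1 alternative. Gene names came from the RefSeq accessions of the probes, matched without versions to a gene table of assembly GRCm38.p6 used for names only (the array design names mm9); of 39429 non-control probes, 27234 were named, as 20659 symbols, and 12195 had no match and were not used for genes.

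The processed signal was put on the log2 scale and each array's 75th percentile over non-control probes subtracted. Control spots and spots with an outlier mark (74 to 273 per array) were left out, and spots of a probe averaged. Probes with a spot well above background on at least 3 arrays were kept (28244, of which 7161 were unnamed), and each symbol was represented by its probe with the highest mean signal, which gave 16055 genes, 43 of them with a value missing on some array. No spot was saturated. Where a gene was not well above background on any array of a group, its fold is given as at least the bright group's mean over a floor: per array, the higher of the lowest signal of any spot well above background and the probe's own signal. Where only some arrays of the dimmer group measured a named gene, its fold between groups is mostly given the same way, a rule added after the data were seen, beside the number of arrays. These floors lay between -7.19 and -5.22 on the normalised log2 scale. Further probes of a gene were compared with the chosen one by direction.

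Groups were compared with limma 3.58.1 (lmFit and eBayes, statmod 1.5.0, R 4.3.3) on all 15 arrays with 1 mean per group, in 6 comparisons: diet in sham mice, diet in mice with 1 kidney, surgery on each diet, the interaction, and both treatments against neither. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison; tests were two-sided, and values after ± are SD where marked. A total of 28 gene lists of kidney cell types, metabolism, inflammation and other tissues, each with at least 5 measured members, were tested with camera at its preset correlation of 0.01, with an estimated correlation beside it, and with fry. These list tests used only members with a value on every array of the fit. With all 15 arrays this left 11 of 12 adipocyte markers, 16 of 17 respiratory chain genes and 14 of 17 antioxidant genes, while member counts and medians include all measured members. The 28 lists, the comparisons, their tests and the first set of alternatives were fixed before the data were examined; the closing section names the alternatives and tests added later. Named genes were the 8 highest and 8 lowest log2 differences among genes that passed (4 and 4 for the interaction and for both treatments against neither), or the lowest p-values up to 5 per direction where fewer than 5 passed, up to 4 members of each list that passed, and a panel of 18 kidney, lipid and injury genes. Other members of the lists that passed the test, the genes that differ between slides, and the genes that passed with a block were named after their values were seen.

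The same comparisons were tested on simulated arrays with 16000 genes of independent noise, some of them changed by a known amount. Of the 2-fold changes, 50.7% were recovered for diet in sham mice, 68.7% for diet in mice with 1 kidney, 70.1% and 68.7% for surgery on the low-fat and high-fat diets, 35.8% for the interaction and 55.2% for both treatments against neither. Of the 1.5-fold changes, 25.4%, 26.9%, 25.4%, 10.4%, 5.97% and 17.9% were recovered, in the same order. These simulations held no slide differences. Each of these sizes was given to 67 genes in a comparison, far fewer than passed between diets on the real arrays. The recovered shares therefore need not hold for the diet comparisons.

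Alternatives changed the normalization (quantile, cyclic loess), the background correction (normexp with an offset of 50), the value table, the filter on dim probes, the choice of probe, the slide as a fixed or random block, the replicate number as a block, the arrays in the fit, array weights, the variance prior and the threshold, and left out each array in turn. Slide as a fixed block took out only the difference between slides 1 and 2 of the high-fat arrays. It did not adjust for the slides of the low-fat arrays or for the scan day. The labels number the mice in each group. Deviations of same-numbered arrays from their group means correlated between -0.153 and 0.435 over 21 pairs; for high-fat sham and 1-kidney mice they correlated at 0.435, 0.122 and 0.331, each above 0.1, so the numbers were also used as a block within the high-fat diet. Replicate 1 of both high-fat groups lay on slide 1, and replicate 3 of both on slide 2.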

Results

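Kidney RNA of 15 male mice was measured on 1-colour Agilent arrays, 1 array per mouse. The mice had received a high-fat or a low-fat (chow) diet for 20 weeks after either removal of the left kidney (uninephrectomy) or a sham operation at 6 weeks of age. The arrays were of low-fat sham mice (4), low-fat mice with 1 kidney (4), high-fat sham mice (3) and high-fat mice with 1 kidney (4); the labels state 6 mice per group. Between 60.5% and 73.4% of the non-control spots of an array were well above background, with means of 70.0% on the high-fat and 63.4% on the low-fat arrays. The number of arrays limits the precision. All high-fat arrays were scanned on scan day 1 (slides 1 and 2) and all low-fat arrays on scan day 2 (slide 3 for sham, slide 4 for 1 kidney). Diet and scan day, and surgery on the low-fat diet and slide, therefore cannot be told apart. The high-fat groups share slides 1 and 2.

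Across the tested genes with a value on every array, the arrays separated first by diet. The first principal component carried 34.7% of the variance and placed the low-fat arrays between -35.64 and -19.56 and the high-fat arrays between 13.15 and 54.53. The second component, with 17.4%, parted the 3 high-fat arrays of slide 1, at 24.69 or above, from the 4 of slide 2, at -5.36 or below. Within the high-fat diet, 4984 genes differed between these slides, among them lower Klk1b22 and Klk1b21 (kallikreins; log2 -2.04 and -1.86), lower Slc22a7 (an organic anion transporter; -1.69), and higher Ace (1.54) and Ucp2 (1.56) on slide 1.

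**Figure D1:**
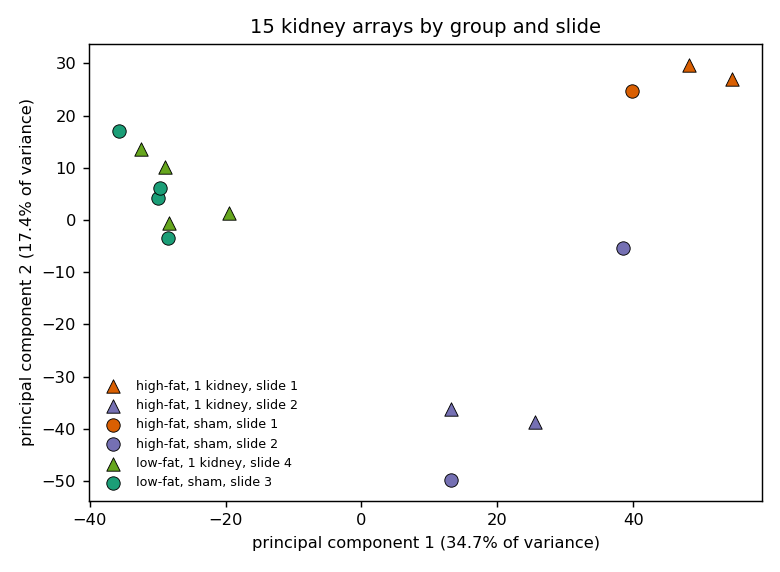
Principal components 1 and 2 of the tested genes with a value on every array, in arbitrary units, with 1 point per array. Circles are sham mice, triangles are mice with 1 kidney, and colours are slides. High-fat arrays lie at 13.15 or above on component 1 and low-fat arrays at -19.56 or below; the high-fat arrays part by slide on component 2.

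The comparison of diets in sham mice asked what 20 weeks of high-fat feeding changed in kidneys left in place. Car3 (carbonic anhydrase 3, abundant in adipocytes) was 3.12-fold lower on the high-fat diet, at 1.81 ± 0.12 (SD, n = 3) against 3.45 ± 0.18 (SD, n = 4) on the normalised log2 scale. Fetub (fetuin B) was 8.26-fold lower, Orm2 (an acute-phase protein) at least 3.41-fold lower, and C4bp (a complement inhibitor) at least 3.59-fold lower, since C4bp was not well above background on any high-fat sham array. Fetub, Orm2 and C4bp belong to 12 liver-type genes whose mean followed that of a list of abundant liver genes over the arrays (r = 0.970). Single genes did not all follow that mean. Among low-fat sham arrays Orm2 was highest on replicate 4 (-3.63), where Ahsg, another of the 12, was lowest (-4.59). Fetub was at -1.20 and -0.83 on low-fat 1-kidney replicates 3 and 4, where Ahsg was high, and at -0.82 and -1.29 on replicates 1 and 2. The listed genes had a median log2 of -0.53 here, 16 of 21 lower and 1 passing. The list called fatty acid oxidation genes here and below also holds PPAR-alpha targets. Of its 26 measured genes 5 passed lower and none higher, against 1190 lower of all 16055 genes. Angptl4 fell by 1.70 (log2), Pex11a by 0.77, Decr1 by 0.57, Acadvl by 0.56 and Ppara, the nuclear receptor of these targets, by 0.41 (adjusted p = 0.0377). The list itself did not pass (adjusted p = 0.101, and 0.890 with an estimated correlation). Of the lymphocyte markers, Cd79b (a B-cell receptor subunit; 2.26-fold) and Cd4 (1.54-fold) were higher.

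In these sham mice 2230 genes passed limma's test at an adjusted p under 0.05, 1040 higher and 1190 lower. With cyclic loess these were 1319 and 1180, and without high-fat sham replicate 3 they were 1304 and 1079. The named increases were Clic6 (a chloride channel protein; at least 7.91-fold), Speer4d (at least 4.64-fold), Hes5 (a Notch target; at least 4.21-fold), Gsx2 (at least 5.47-fold), Hyal6 (at least 2.88-fold), Olfr339 (at least 7.27-fold), Mpp2 (at least 1.46-fold) and Celf6 (at least 2.30-fold). Apart from Clic6, on 1 of 4, none of these 8 genes was well above background on any low-fat sham array. Orm2, Wfdc21 and Fcna were well above background on 1 of 3 high-fat sham arrays. The named decreases also took in Serpina4-ps1 (at least 3.28-fold), Wfdc21 (at least 8.15-fold), Fcna (a ficolin; at least 4.18-fold), Retnla and Cfd (adipsin). The groups overlapped for the last 2: Retnla was at -4.01 ± 2.50 (SD, n = 3) against -0.56 ± 0.96 (SD, n = 4) and Cfd at -0.77 ± 2.14 against 2.12 ± 0.77, and neither passed without high-fat sham replicate 1 (adjusted p = 0.121 and 0.114) or 2 (0.202 and 0.148). Extracellular matrix genes had 5 of 20 members lower (among them Timp1 -1.78, Dcn -0.81 and Sparc -0.77), with an adjusted p of 0.101 for the list. Antioxidant genes had 4 of 17 lower, including Gstm1 (-1.23), Gclc (-1.18) and Hmox1 (-0.83), and 1 higher, Cat (0.60). The mineralocorticoid receptor gene Nr3c2 (-1.39) and the sodium channel subunit Scnn1a (-0.74) were lower, and Ace (2.15) was higher. Of 28 gene lists, lymphocyte markers were higher (median log2 0.62, 13 of 15 members higher) and adipocyte markers lower (median -1.78, 11 of 12 lower, 4 passing: Cfd, Car3, Adig at -0.95 and Adipor2 at -0.41), each with an adjusted p of 0.0135 at the preset correlation and 0.890 with an estimated correlation; without high-fat sham replicate 1 these were 0.0573 and 0.0966 at the preset one. The test of the adipocyte list left out Car3, which lacked a value on high-fat 1-kidney replicate 2. Apart from Ppara, none of the other 17 genes of the fixed panel, which include Scd1, Fasn, Cpt1a, Cd36, Ccl2, Havcr1 and Lcn2, passed the test. With slide as a random block 14 of the 2230 genes passed: Car3 (adjusted p = 0.0171) was lower and 13, among them Gsx2 (0.0225), Olfr339 (0.0240) and Speer4d (0.0262), were higher, while the adjusted p was 0.288 for Ppara and 0.0691 for Fetub. Further probes of the genes that passed pointed the same way in 66.1% of cases, against 57.6% for genes that did not pass.

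The same comparison in mice with 1 kidney gave the diet effect after uninephrectomy. Ahsg (fetuin A, made by the liver) was at least 33.5-fold lower on the high-fat diet, and 6 major urinary protein genes were lower too, Mup20 by at least 33.2-fold, Mup3 by at least 10.8-fold, and Mup4, Mup17, Mup18 and Mup19 by 35.8-fold to 45.0-fold. Ahsg, Mup20 and Serpina3k were well above background on 1 of 4 high-fat arrays. Levels were spread widely within the low-fat group, with Ahsg at -1.25 ± 3.12 (SD, n = 4) against -6.81 ± 0.55 (SD, n = 4). Mup18 ran from -2.49 to 4.57 on the low-fat arrays, so its fold rests on the high ones. On the low-fat diet Ahsg was highest in sham replicate 1 (0.95) and in 1-kidney replicates 3 (1.29) and 4 (1.54). Of 21 measured genes of a separate list of abundant liver genes 2 passed lower and 1 higher, with a median log2 of -0.404. S100a8 and S100a9, the calprotectin genes of neutrophils, were 3.49-fold and 3.41-fold lower. Car3 was lower by 1.73 (log2). Of the lymphocyte markers, Cd3e (2.38-fold), Cd79b (2.22-fold), Cd27 (at least 1.49-fold) and Cd4 (1.61-fold) were higher. The T-cell genes Cd3d, Cd3g and Lck overlapped between the diets, Lck at -1.95 to -1.08 on the low-fat and -1.78 to -1.10 on the high-fat diet.

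In mice with 1 kidney 2278 genes passed limma's test, 1231 higher and 1047 lower; with quantile normalization these were 1157 and 1341. Beside the genes above, Serpina3k was at least 12.2-fold lower; Syt10 (at least 31.7-fold), Hes5 (at least 4.74-fold), Mc3r (at least 2.05-fold), Gsx2 (at least 5.22-fold), Mpp2 (at least 2.13-fold), Speer4d (at least 5.03-fold), Casp14 (at least 7.33-fold) and Clic6 (at least 7.04-fold) were the named increases. Syt10 was well above background on 2 of 4 low-fat arrays, Casp14 and Clic6 on 3 of 4. The Syt10 mean hides a spread from -5.31 to 1.76 among the 4 high-fat arrays. Mup genes are near-identical copies, so their probes may share transcripts and each copy's value is uncertain. Gstm1 (-1.11), Gclc (-1.24), Angptl4 (-1.02), Nr3c2 (-0.86) and Scnn1a (-0.54) were again lower, and Pck1 (the gluconeogenic enzyme; 1.09), Ace (1.70) and Dhcr7 (cholesterol synthesis; 1.26) again higher. Lymphocyte markers were higher as a list (median log2 0.36, 13 of 15 higher, 5 passing; adjusted p = 0.0205, but 0.963 with an estimated correlation), and blood cell markers lower (median -0.41, 8 of 10 lower, 3 passing; adjusted p = 0.0216, but 0.963 with an estimated correlation). With slides 1 and 2 as a fixed block neither list passed (adjusted p = 0.0539 and 0.0612), nor without high-fat replicate 3 (0.0700 and 0.139). None of the 18 panel genes passed. With slide as a random block 26 of the 2278 genes passed, 4 of them lower, including Car3 (adjusted p = 0.0143), and 22 higher, including Gsx2 and Casp14; Ahsg had an adjusted p of 0.324. Without the 3 low-fat arrays high in Ahsg, chosen after the data were seen, 333 genes passed and Ahsg was at -2.89 (adjusted p = 0.0787), while 67.8% of further probes of the 2278 genes pointed the same way, against 58.2% for the others.

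Effects of diet in the sham and 1-kidney mice ran together. Car3, Gsx2, Hes5, Clic6, Mpp2, Speer4d, Cd79b and Cd4 passed in both comparisons with the same sign. In all, 755 genes were higher and 665 lower in both, against 79.7 and 77.6 for independent lists, and none passed in opposite directions. Across genes, which are not independent replicates, Pearson's r of the log2 differences was 0.817 and Spearman's rho 0.811; the comparisons share no array but share the scan days.

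**Figure D2:**
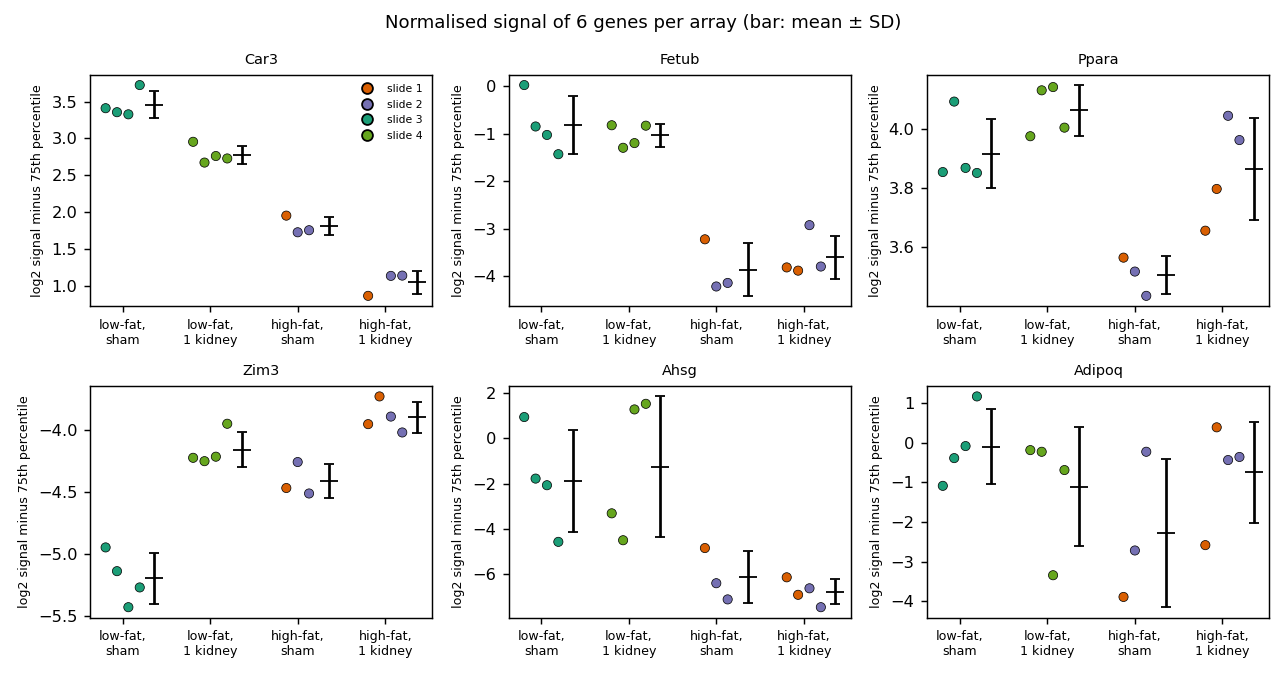
Normalised signal of 6 genes (log2 signal minus the 75th percentile of the array) per array, by group; bars are mean ± SD and colours are slides. Car3 and Fetub lie lower on both high-fat groups, and Zim3 lies higher after uninephrectomy on both diets, though it passed on the low-fat diet alone. Ahsg varies most among the low-fat arrays, from -4.59 to 1.54.

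Uninephrectomy on the low-fat diet asked how the remaining kidney differed from a sham kidney at 20 weeks. Zim3, a zinc-finger gene, was higher in the remaining kidney, 2.05-fold, at -4.16 ± 0.14 (SD, n = 4) against -5.20 ± 0.20 (SD, n = 4), with no overlap between the groups (adjusted p = 0.0175). It was well above background on 3 of 4 sham arrays. Extracellular matrix genes lay lower as a list (median log2 -0.35, 19 of 20 members lower), including Timp1 (-1.05), Col1a1 (-0.63), Col3a1 (-0.57) and Dcn (-0.56), none of which passed alone; the list's adjusted p was 4.5e-10, and 0.219 with an estimated correlation. Immediate-early genes were lower too (median -0.26, 13 of 15 lower; adjusted p = 5.51e-05, but 0.219 with an estimated correlation), with Egr1 at -1.23. Fatty acid oxidation genes (median 0.16, 23 of 26 higher; adjusted p = 0.00153, but 0.442 with an estimated correlation, and 0.557 at the preset correlation without sham replicate 1) and respiratory chain genes (median 0.16, 17 of 17 higher; adjusted p = 0.00134, but 0.319 with an estimated correlation) were higher.

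Zim3 was the 1 gene that passed limma's test; 519 genes had an unadjusted p under 0.05. The next lowest p-values belonged to Padi1 (0.81), Sorcs1 (0.92), Olfr1232 (at least 1.20-fold), Scgb2b20 (0.58) and, lower, Car3 (-0.68), Heyl (-0.84), Lbhd2 (at least 1.02-fold), Olfr225 (at least 1.20-fold) and Lmx1a, which was not well above background in either group, at adjusted p-values of 0.384 to 0.613. In all 15 lists passed at the preset correlation and none with an estimated one, whose lowest adjusted p was 0.194. Beside those above, proximal tubule, distal nephron, male-biased kidney and circadian clock genes were higher, the last with Per2 at 0.81, and podocyte, endothelial, tubular injury, inflammatory, lymphocyte, adipocyte and skeletal muscle genes lower. Their medians ran from -0.63 (adipocyte markers) to 0.31 (male-biased kidney genes), and their adjusted p-values with an estimated correlation from 0.194 to 0.595. The lower adipocyte markers rested on 1-kidney replicate 3, at -1.44 against 0.55 to 0.63 on the other arrays of its group; without it their median was -0.15 (adjusted p = 0.950). The median of the circadian genes turned to -0.04 without sham replicate 3, and that of the inflammatory genes to 0.02 without 1-kidney replicate 1. With the high-fat slides as a fixed block the inflammatory, lymphocyte, circadian and adipocyte lists did not pass (adjusted p = 0.0579, 0.0579, 0.0729 and 0.0661). Among all list members 0 passed over all genes tested and 5 when adjusted over the list alone. None of the 18 panel genes passed. Each group lay on its own slide, and no gene passed with slide as a random block (adjusted p = 1.00 for Zim3); leaving out any 1 of the low-fat arrays other than sham replicate 1 also left 0 genes.

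Uninephrectomy on the high-fat diet asked the same under high-fat feeding. Fatty acid oxidation genes lay higher in the remaining kidney as a list (median log2 0.31, 25 of 26 members higher), with Cyp4a14 at 1.67, Slc25a20 at 0.65 and Ppara at 0.36; the list's adjusted p was 1.19e-06, and 0.662 with an estimated correlation, and its median was 0.18 without sham replicate 2. Immediate-early genes lay lower (median -0.36, 10 of 15 lower; adjusted p = 0.00557, but 0.662 with an estimated correlation, and 0.124 at the preset one without 1-kidney replicate 4), with Egr1 at -1.92 and Fos at -1.55. Adipocyte markers lay higher (median 0.84, 11 of 12 higher; adjusted p = 0.00118, but 0.662 with an estimated correlation), with Cidec at 1.88; their median was 0.36 without sham replicate 1 (adjusted p = 0.535), 0.69 without 1-kidney replicate 2 (0.374) and 1.97 without sham replicate 3 (1.18e-08). Aim2, a sensor of cytosolic DNA, had the lowest p, was not well above background on any array of mice with 1 kidney (at least 1.25-fold lower than in sham kidneys), and did not pass (adjusted p = 0.0804).

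No single gene passed limma's test on the high-fat diet, and 747 had an unadjusted p under 0.05. Zim3, which passed on the low-fat diet, was higher by a log2 of 0.51 here and did not pass. It lay at -4.02 to -3.73 in mice with 1 kidney against -4.51 to -4.26 in sham mice. The other named values, none of which passed, were Foxe1 (at least 2.09-fold), Kcnk9 (at least 1.61-fold), Olfr681 (log2 1.25), Foxe3 (at least 1.59-fold, 2 of 3 sham arrays well above background) and Gulo (2.27) above sham, and Car3 (-0.77), Il5ra (-0.84), Nap1l3 (-0.53) and Slc9a4 (at least 1.32-fold) below. With slides 1 and 2 as a fixed block 0 genes passed (adjusted p = 0.240 for Aim2). Slide 1 holds 1 sham array, so values within it rest on that array. The median of the fatty acid oxidation genes was 0.30 with the block, 0.11 within slide 1 and 0.51 within slide 2, that of the immediate-early genes -0.29, 0.07 and -0.71, and that of the adipocyte markers 1.05, 2.57 and 0.47. Of list members, 0 passed over all genes and 1 when adjusted over the list alone, and none of the 18 panel genes passed. With the replicate number as a block within the high-fat groups, a fit chosen after the data were seen, 24 genes passed, 23 higher, led by Itga2b (0.92, adjusted p = 0.0240), and Aim2 lower (adjusted p = 0.0478); these numbers partly coincide with the slides.

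**Figure D3:**
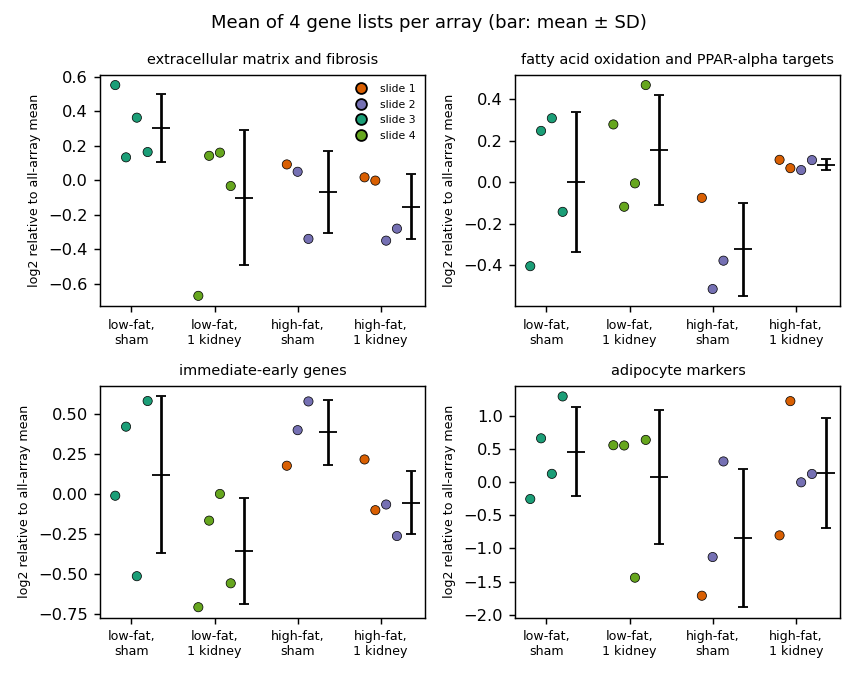
Mean of 4 gene lists per array (log2 relative to each gene's mean over all arrays), by group; bars are mean ± SD and colours are slides. Immediate-early genes average lower in mice with 1 kidney on both diets, and adipocyte markers vary most between arrays, with low-fat 1-kidney replicate 3 at -1.44.

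Whether the effect of surgery depended on diet was tested as an interaction. Surgery on the low-fat diet coincides with slide, so the interaction also carries that slide difference and cannot be told apart from it. Adipocyte markers differed most as a list: the effect of uninephrectomy was higher on the high-fat than on the low-fat diet by a median log2 of 1.60, with Cidec at 2.77 and Retn at 2.56. Its adjusted p was 2.48e-06, and 0.599 with an estimated correlation. The median was 0.94 without low-fat 1-kidney replicate 3, 0.88 without high-fat sham replicate 1 and 2.73 without high-fat sham replicate 3. Extracellular matrix genes (median 0.28, 18 of 20 higher; adjusted p = 0.00192, but 0.798 with an estimated correlation) and skeletal muscle markers (median 0.10, 5 of 7 higher; adjusted p = 0.0272, but 0.599 with an estimated correlation) lay the same way, with Timp1 at 1.10. With slides 1 and 2 as a fixed block neither of these passed (adjusted p = 0.133 and 0.258), while the adipocyte markers did (7.44e-05). Without low-fat 1-kidney replicate 1 the matrix list had a median of 0.11 and did not pass, and without high-fat sham replicate 3 the muscle list had -0.10 (adjusted p = 0.222). No gene passed limma's test, with 219 at an unadjusted p under 0.05. The lowest p-values belonged to Nap1l3 (-0.62), Sorcs1 (-0.77), and Aim2, Olfr225, Foxe1, Lcn10, Atp1a4, Olfr469, Rims4 and Olfr1316, the last 8 not well above background in at least 1 group, each with an adjusted p of 1.00. Across genes the effects of surgery on the 2 diets had a Pearson's r of 0.251 and a Spearman's rho of 0.305.

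The mice with both treatments were also compared with the mice that had neither. Calprotectin genes were lower with both treatments, S100a8 by 5.48-fold, at -2.95 ± 0.59 (SD, n = 4) against -0.50 ± 0.48 (SD, n = 4), and S100a9 by 5.20-fold. Extracellular matrix genes were lower, 6 of 20 passing with none higher, among them Lox (at least 2.93-fold), Timp1 (3.33-fold), Dcn (2.01-fold) and Col1a1 (1.91-fold). The liver genes Mup20 (at least 19.7-fold), Ahsg (at least 21.8-fold), Mup18 (27.0-fold) and Mup3 (at least 8.02-fold) were lower, and Syt10 (at least 28.6-fold), Clic6 (at least 10.5-fold), Hyal6 (at least 3.72-fold) and Speer4d (at least 4.93-fold) higher. Without low-fat sham replicate 1 none of these liver genes passed: Ahsg was at -3.99 (adjusted p = 0.0610) and Mup20 at -4.20 (adjusted p = 0.0849). In all 3131 genes passed limma's test, 1664 higher and 1467 lower. With quantile normalization these were 1591 and 1884. The lists of extracellular matrix genes (median log2 -0.51, adjusted p = 0.0407) and blood cell markers (median -0.54, adjusted p = 0.0127) were lower. Each had an adjusted p of 0.988 with an estimated correlation. With slides 1 and 2 as a fixed block their adjusted p was 0.159 and 0.0366, and without high-fat 1-kidney replicate 3 it was 0.367 and 0.116. Of list members, 81 passed over all genes and 89 when adjusted over the list alone; these counts were 58 and 70 for diet in sham mice, 52 and 60 in mice with 1 kidney, and 0 and 0 for the interaction. With slide as a random block 84 of the 3131 genes passed, 76 higher, including Speer4d, Clic6 and Hyal6, and 8 lower, including Car3 and Fetub. Without the 3 low-fat arrays high in Ahsg 1375 genes passed.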

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

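The slide test, the brightness test between diets, the correlation of liver-type genes over arrays and the fit without 3 low-fat arrays were chosen after the results were seen; the predictions of the other tests were written before their own results were seen.

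Many genes passed the test between diets, Car3 and Gsx2 among them, and scan day parts the diets as well. Slides 1 and 2, both of high-fat arrays scanned on 1 day, differed in 4984 genes (2343 higher and 2641 lower on slide 1). Of 34 splits of the high-fat arrays 2, the slides included, gave as many, so this count fits an arbitrary grouping. With slide as a random block, 14 and 26 of the genes that passed between diets still passed. A slide difference could account for many of the genes that passed between diets, and this test cannot tell. Scan day coincides with diet, so it could account for any of them, those that passed with the block included. Further probes pointed the same way for 66.9% between diets and 61.9% between slides, between the limits set for hybridisation differences and for changes in RNA, so neither can be told. The share of genes that passed among the brightest 25% of genes was 0.848 times that among the dimmest 25% between diets (19.3% and 22.8%) and 2 times between slides (33.4% and 16.7%), which argues against a dim-signal floor as the whole cause. For dim genes a floor stays open: with normexp 161 and 316 genes passed between diets, and with no filter 3626 of 4850 were lower in sham mice. The floor lay at -6.07 or below on the high-fat arrays and at -5.94 or above on the low-fat arrays. Such a floor would make dim genes look lower on the high-fat diet, not higher. In sham mice 7 of 8 named increases were not well above background on the low-fat diet, so their folds are bounds. Of the 35 splits of the arrays only the real 1 reached 2230 genes in sham mice, 1 of 35 reached 2278 in mice with 1 kidney, and 1 of 35 reached 3131 for both treatments against neither; the splits do not part diet from scan day.

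Adipocyte markers varied between arrays within groups, Adipoq from -3.89 to -0.23 in high-fat sham mice. Varying amounts of fat tissue in the dissected kidneys could account for this: the median pairwise correlation of the residuals of 6 markers was 0.869, above the limit of 0.6 written beforehand. More lipid storage in kidney cells was not told apart. Lipid-storage genes followed the markers at a median correlation of 0.483, from -0.284 for Fabp3 and 0.036 for Plin2 to 0.700 for Cd36 and 0.781 for Scd1. Fat tissue can express such genes too, so this median cannot part the 2 explanations. Both explanations leave the diet and surgery differences of the adipocyte list open.

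Liver-type genes (6 Mup genes, Ahsg, Serpina3k, Fetub, Serpina4-ps1, C4bp, Orm2) were lower on the high-fat diet in at least 1 comparison, and Ahsg and the Mup genes were highest on 3 of the 8 low-fat arrays. Liver RNA in these kidney samples is a candidate explanation: a separate list of 22 abundant liver genes, 21 of them measured and their values unseen when it was written, had a median log2 difference of -0.404 in mice with 1 kidney and a median residual correlation of 0.449, which cannot tell. Mean residuals of these 12 genes and of the listed genes correlated at 0.970 over 15 arrays (permutation p = 0.0013), and Alb stood at 1.34, 2.00 and 2.22 on sham replicate 1 and 1-kidney replicates 3 and 4, against -0.67 to -0.07 on the other low-fat arrays. Without these arrays Ahsg had an adjusted p of 0.0787 and Orm2, in sham mice, of 0.0805, while Fetub (-2.76) and Car3 (-1.66) still passed in sham mice. This cannot tell either, since the arrays were left out for their high Ahsg and fewer arrays remained. Genes that passed fell to 665 in sham mice and 333 in mice with 1 kidney. Orm2 on the sham array left out (-4.34) lay within the range of the other low-fat sham arrays (-4.93 to -3.63). A lower expression of these genes in the kidney on the high-fat diet was not tested apart from liver RNA.

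High-fat sham mice, with 3 arrays, were too few to be tested for outlying samples. The 75th percentile of their signal ran from 700 to 3433. In the other groups, samples far from the others of their group numbered 25 of 524 groups tested, 4.77%, and chance gives about 1 in 20. In low-fat sham mice these were the SD of the negative controls (4.94, replicate 3), Aim2 (-6.63, replicate 1), Cd3d (-2.84, replicate 3), Cd4 (-0.417, replicate 2), Foxe3 (-6.03, replicate 2), Ms4a1 (-6.44, replicate 4), Ppara (4.09, replicate 2) and Rims4 (-6.11, replicate 3). In low-fat mice with 1 kidney they were replicate 3 for the male-biased kidney genes (0.505), the adipocyte markers (-1.44), Adipoq (-3.35), Plin1 (-5.32) and Retn (-3.12), and replicate 4 for Nap1l3 (-3.63) and Zim3 (-3.95). In high-fat mice with 1 kidney they were Btg2 (-1.24), Dcn (2.87) and Timp1 (-3.32) of replicate 2, Fetub (-2.92), Il5ra (-3.54), Sqle (2.84) and Syt10 (-5.31) of replicate 3, Cd4 (0.959) and Lox (-8.09) of replicate 4, and Retn (-2.43) of replicate 1. Aim2, Foxe3 and Rims4 in low-fat sham mice and Lox in high-fat mice with 1 kidney were not well above background on any array of the group.

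At the preset correlation the interaction passed for the extracellular matrix genes (adjusted p = 0.00192), the adipocyte markers (2.48e-06) and the skeletal muscle markers (0.0272). None passed with an estimated correlation (0.798, 0.599 and 0.599). With the high-fat slides as a fixed block the adipocyte markers passed (7.44e-05), and the matrix and muscle lists did not (0.133 and 0.258). Surgery on the low-fat diet coincides with slide, so these passes cannot tell a diet-dependent effect of surgery from a slide difference.

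Counting the real grouping itself, as many lists as it gave were reached in 31 of 35 splits of the arrays for diet in sham mice, 30 of 35 in mice with 1 kidney, 17 of 35 for surgery on the high-fat diet, 28 of 35 for both treatments against neither and 78 of 100 for the interaction, so these list counts fit an arbitrary grouping. The regroupings took no account of slides 1 and 2, between which 4984 genes passed, so those of high-fat arrays may carry slide differences. With these slides as a fixed block surgery on the high-fat diet gave 8 lists and the interaction 1. For surgery on the low-fat diet only the real grouping of 35 reached its 15 lists, and the highest other split gave 14. For genes, 3 of 35 splits, the real one included, gave as many as surgery on the low-fat diet (Zim3). For surgery on the high-fat diet and the interaction 35 of 35 and 100 of 100 reached the real count of 0. Any grouping reaches 0, so these 2 comparisons cannot tell. For surgery on the high-fat diet 10 other splits passed genes, at most 5170 in the split that sets slide 1 and sham replicate 2 against the rest, and a regrouping for the interaction reached 2543. With the real one included, the correlation of the diet effects was reached by 1 of 100 regroupings and that of the surgery effects by 2 of 100. Of 34 splits of the high-fat arrays 2, the slides included, gave as many genes as the slides. The other, at 5685, was slide 2 without sham replicate 2. By this test the count between slides also fits an arbitrary grouping, though that split differs from the slides by 1 array.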

How the results depend on the processing

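Of 21 settings tried beside the 15 that leave out 1 array, those with cyclic loess, normexp, probes above background on all arrays, the replicate block within the high-fat groups, single slides and left-out pairs or sets of arrays were chosen after seeing the data. Settings that gave more genes are alternatives and not findings. No named gene that passed changed direction in a setting where it had a value. Of 63 passes of named genes, counted once per comparison, 63 were kept with the authors' table, 61 with quantile normalization, 10 with slide as a random block and 8 with normexp; 57 had a value with the filter on every array of a group and 28 with that on all arrays. The cause of each change was not tested unless stated. Counts below are in the order diet in sham mice, diet in mice with 1 kidney, and both treatments against neither, where 2230, 2278 and 3131 genes passed; the main counts for surgery on the low-fat and high-fat diets and the interaction were 1, 0 and 0 genes, and 15, 3 and 3 lists, beside 2 lists in each of the first 3 comparisons.

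Genes that passed numbered 161, 316 and 481 with normexp, and 4850, 3596 and 5177 with no filter on dim probes. The last setting split into 1224 higher and 3626 lower in sham mice, and 1292 and 2304 in mice with 1 kidney. Counts were 14, 26 and 84 with slide as a random block, and 557, 560 and 835 at 2-fold. With slides 1 and 2 of the high-fat arrays as a fixed block, which does not adjust for scan day, the counts were 4474, 4101 and 5067. They were 4224, 5358 and 5830 with the replicate block within the high-fat groups, 4838, 7712 and 8285 with the high-fat arrays of slide 1 alone, and 665, 333 and 1375 without the 3 low-fat arrays high in liver genes (258 of the 333 higher). In mice with 1 kidney 1231 were higher and 1047 lower, against 1157 and 1341 with quantile normalization and 120 and 196 with normexp. Single changes were 3458 and 4779 with every probe as a feature and 5772 and 6439 with array weights (mice with 1 kidney, both against neither), and, in sham mice, 1181 with only the groups compared, 3660 with slide 2 alone and 1375 without the dimmest and brightest high-fat sham arrays. Slide 1 alone, and leaving out the dimmest and brightest, each keep 1 high-fat sham array, so comparisons with that group there test a single array assumed to vary like the other groups.

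For surgery on the low-fat diet 0 genes passed with normexp, probes above background on all arrays, the random block, the groups alone, the trended prior, the replicate block, either slide alone, or without the 3 liver-high arrays; 2 passed with quantile normalization and with the replicate block within the high-fat groups, 101 with array weights and 82 at an unadjusted p under 0.01 and 1.5-fold. For surgery on the high-fat diet 1 passed with cyclic loess, 24 with the replicate block within the high-fat groups, 3 with slide 1 alone, 178 with slide 2 alone, 34 without the dimmest and brightest high-fat sham arrays, 1 without the 3 liver-high arrays and 101 at the unadjusted threshold; the 3 and the 34 compare 1 sham array, and the 178 compares 2 arrays with 2. For the interaction these were 2 with slide 1 alone, 4 without the dimmest and brightest arrays and 34 at the unadjusted threshold.

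Lists that passed were 0 in all 6 comparisons with an estimated correlation and 0 with fry in all but both treatments against neither (2). For both against neither 1 list passed with quantile, cyclic loess, the fixed slide block, the replicate block, without the dimmest and brightest arrays and without the liver-high arrays, and 0 with no filter and with slide 1 alone. Diet in sham mice gave 1 list with no filter and 5 with slide 2 alone. Diet in mice with 1 kidney gave 4 with normexp and with the replicate block within the high-fat groups, 1 with no filter and with slide 2 alone, and 0 with the fixed block. Surgery on the low-fat diet gave 9 with slide 1 alone and without the liver-high arrays. Surgery on the high-fat diet gave 5 with no filter, 8 with the fixed block and 7 with slide 2 alone. The interaction gave 1 with the fixed block and with slide 2 alone, 5 with the replicate block within the high-fat groups, and 6 with slide 1 alone and without the liver-high arrays.

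The correlation of the diet effects (0.817) was 0.653 with slide 2 alone and 0.723 without the dimmest and brightest arrays. That of the surgery effects (0.251) was 0.136 with no filter, 0.133 with slide 2 alone and 0.130 without the liver-high arrays.

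Leaving out 1 array at a time gave 1210 to 2718 genes in sham mice, 1297 to 3306 in mice with 1 kidney, 0 to 1 for surgery on each diet and for the interaction, and 1971 to 4218 for both against neither. Lists ran from 0 to 4, 0 to 3, 12 to 17 (surgery on the low-fat diet), 2 to 15 (high-fat diet), 1 to 8 (interaction) and 0 to 4. Correlations ran from 0.717 to 0.817 for diet and 0.188 to 0.275 for surgery. In sham mice the largest losses came without low-fat sham replicates 1 (1393), 2 (1409) and 3 (1219) and high-fat sham replicate 2 (1210). In mice with 1 kidney they came without low-fat replicates 1 (1350), 3 (1405) and 4 (1297) and high-fat replicates 1 (1486) and 2 (1363). For both against neither they came without low-fat sham replicates 1 (2030) and 3 (2076) and high-fat 1-kidney replicate 2 (1971). Of the 15 lists for surgery on the low-fat diet, the pass was lost without 1 array in 8 cases for circadian genes, 5 for distal nephron genes, 4 each for lymphocyte and adipocyte markers, 3 for inflammatory genes, 2 for fatty acid oxidation genes, 1 each for podocyte and male-biased genes, and 0 for the others. Aim2 passed for surgery on the high-fat diet without low-fat sham replicate 1 (1 gene, and 1 for the interaction), and 15 lists passed there without high-fat 1-kidney replicate 1.

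Numbered replicates as a block in all groups gave 1799, 2139 and 2994 genes and 0 for each surgery comparison. Scan day as a block was not run: it coincides with diet and is constant within each surgery comparison. Signal limits the dim genes, since 60.5% to 73.4% of spots were well above background.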

Other observations

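The surgery effect averaged over diets and the comparison of slides were chosen after the data were seen; the prediction for the average was written before its result was seen.

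Averaged over diets, with the high-fat slides as a block, 4 genes passed for surgery, which cannot tell whether a shared surgery effect exists. The block does not adjust for the slides of the low-fat arrays, so genes and lists in this average carry that slide difference. Zim3 was higher in the remaining kidney (0.77, adjusted p = 0.0194), as were Col27a1, a collagen gene (0.85, 0.0454), and Pramel25 (0.50, 0.0454), and Car3 was lower (-0.72, 0.0454). Without the block their log2 differences on the low-fat and high-fat diets were 1.03 and 0.51 for Zim3 and 0.80 and 1.00 for Col27a1. They were 0.48 and 0.40 for Pramel25, and -0.68 and -0.77 for Car3. In that average 1612 genes had an unadjusted p under 0.05. Of the lists, 12 passed at the preset correlation and 0 with an estimated one; fatty acid oxidation genes were higher (median log2 0.22, adjusted p = 2.88e-06, but 0.382 with an estimated correlation) and extracellular matrix genes lower (-0.28, adjusted p = 4.52e-06, but 0.382 with an estimated correlation).

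Further genes of the fixed lists passed in both diet comparisons, named after their values were seen. Slc5a1, a sodium-glucose transporter, was higher by 0.91 in sham mice and 1.17 in mice with 1 kidney, Zfp36 by 1.61 and 1.94, Tnf by 1.28 and 1.02, Cd44 by 0.71 and 0.85 and Pvalb by 1.15 and 1.11. Slc34a3, a phosphate transporter, was lower (-0.92 and -1.05), as were Igf1 (-0.51 and -0.50), Clu (-1.28 and -0.76) and Asns (-1.11 and -0.79). With slide as a random block only Car3 of the list members still passed in both.

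Between slides 1 and 2 of the high-fat arrays macrophage markers were higher on slide 1 (median 0.54, 9 of 19 passing; adjusted p = 0.00378, but 0.950 with an estimated correlation). Hbb-bs (1.63), Nr1d1 (1.55) and Dtx3 (1.74) were higher on slide 1, and Ppp5c (-2.20) and Ugt2b5 (-1.88) lower. In the liver-gene list Hp was lower in sham mice (-2.24, adjusted p = 0.0236), and in mice with 1 kidney Hpx (-3.53, 0.0370) and Ambp (-1.44, 0.0338) were lower and Cyp2c29 (0.83, 0.0202) higher.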
